A study of Homo sapiens with 9 samples.

How the data were processed

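Chromatin accessibility was measured by ATAC-seq in 9 libraries of human postnatal thymocytes, 1 per donor and dose, from 3 donors. Per the labels' protocols, CD28+ immature single-positive cells (CD4+, CD28+, CD3- and CD8-) were sorted and cultured at 100000 cells per well in 100 µL of MEMα with 20% fetal calf serum, 10 ng/ml SCF and IL-7. The cells were left unstimulated or were given 2.5 or 10 µL of ImmunoCult, a commercial reagent that activates T cells, for 24 h. Transposition used 0.01% digitonin, and 75 bp reads were sequenced single-end or paired-end, per the labels' protocols, which do not say which layout each library had. The submitters' processing notes name GRCh38/hg38, Trimmomatic, Bowtie2 2.2.6, SAMtools, bedtools, MACS2 and DESeq2, with no role for any of them.

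The deposited raw table gives counts per region for 72671 accessible regions shared by all 9 libraries, each with an end 501 bp past its start. Its values are whole numbers, so they were taken as raw counts. How reads were counted, how peaks were merged and which filters were used is not stated in the labels. Coordinates are printed as the authors' table gives them, and whether that table counts from 0 or from 1 is not stated. No region passed the end of a chromosome of hg38. Of the authors' gene identifiers in that table, 99.47% of those found in GENCODE 44 overlapped the same gene there, so GENCODE 44 and hg38 were used for positions and sequence.

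The authors' normalized table was read as other values than counts, since the decimal points had been lost and only the digits could be read. Within each library those digits were proportional to the raw counts in 100% of the regions read, which gave back 1 factor per library. These factors were 0.896 to 0.914 times the DESeq2 size factors computed from the counts. The normalized values were used only for a limma fit planned as another test, and 1 column of that table, an exact repeat of another, was not used.

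Regions on chromosome Y and at XIST or TSIX, 116 in all, were left out of every computation for privacy, which left 72555. A region was assigned to the protein-coding gene with the nearest transcription start site (TSS) within 100 kb of its midpoint, which held for 57355 regions, and 17565 regions (24.17%) were promoters, with a midpoint within 1 kb of a TSS. The distance of a region to a TSS says nothing on which gene it acts on. Regions were called mitochondrial-like where at least 20% of their 31 bp stretches also occur in the mitochondrial genome of hg38. Replication-dependent histone genes were taken by symbol, after seeing the data, and the sequence that their promoter regions share was counted in 31 bp stretches found in more than 1 of them.

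The following choices were made before the data were examined. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided and robust, with TMM factors, a low-count filter by group (filterByExpr) and 1 fit of all 9 libraries with the dose as the only term. The filter left 70538 regions. The comparisons were 10 µL against unstimulated, 2.5 µL against unstimulated, and 10 against 2.5 µL, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 values of the fit, with edgeR's default prior count. A prior count of 2 was used only for log2 CPM, in offsets and in differences within a donor. Levels are TMM-scaled CPM as mean ± SD over 3 libraries per group.

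The regions of 18 gene lists and of 5 loci (TRA/TRD, the interval from TRAC to DAD1, TRB, TRG and the HOXA cluster) were compared with all other regions by camera of limma 3.58.1, with its preset correlation of 0.01 between regions. Adjustment was over the lists, or the loci, of 1 comparison. Camera with an estimated correlation and fry were planned beside it. The share of promoters among called regions and 22 consensus motifs in the central 200 bp were compared with uncalled regions by Fisher's exact test, the motifs against regions matched on GC content in bins of 5%. Regions were named by a fixed rule. It took the 10 largest rises and the 10 largest falls past the threshold, with mean CPM at or above the median, assigned to a named gene, 1 region per gene and with the same direction in every donor. It added up to 4 regions with the smallest p of each list that held a call or passed camera, the region with the smallest p of each locus, and the 5 regions with the smallest p where fewer than 5 regions rose or fell. Items named outside this rule are said to have been chosen after their values were seen.

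Other planned settings were the donor as a replicate block, DESeq2 1.42.0, DESeq2 size factors or library size alone in edgeR, loess offsets, no filter, a filter of 30 counts in 3 libraries, the 6 libraries of a comparison alone, autosomes alone, an adjusted p under 0.01, and leaving out each donor or library in turn. For lists, loci, promoters and motifs they also covered promoter regions alone, a distance of 25 kb, promoters within 2.5 kb, and windows of 400 bp. The labels name the donor of every library, so equal numbers mark the same donor. Deviations from the group means correlated at 0.136 to 0.558 between the libraries of a donor, all above 0.1.

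The deposited totals showed 1 shallow library, the unstimulated library of donor 2. Further settings, chosen after seeing the data, therefore used the replicate block without that library (8 libraries, 71918 regions tested). They also combined it with loess offsets, GC offsets (a loess of each library on GC content), library size alone, DESeq2, leaving out donor 2, leaving out 1 further library, and thinning every library to 2455360 counts. Another of these settings, voom with library weights, used the replicate block on all 9 libraries. For lists and loci the further settings added the block with an estimated correlation, and promoter regions of a list against other promoters. In the fit without the shallow library the donors with both an unstimulated and a 10 µL library are 2, donors 1 and 3, so the same direction in every donor could be checked in those alone.

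The tests were tried first on simulated counts for 10 µL against unstimulated. These were drawn from donor means and library totals, with the dispersions of the fit with the replicate block. Of 70538 regions, 100 were changed by a fold of 2 and 100 by a fold of 4, all with signal above the median. The counts thus followed the model of the replicate block, which favours it over the planned test, and recovery at lower signal was not tried. The planned test recovered 0% and 34% of the changed regions with 0 false calls. The replicate block recovered 44% and 93% with 6 false calls, the block without the shallow library 41% and 94% with 7, and DESeq2 2% and 60% with 0.

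Deposited totals ran from 120308 to 7309502 counts per library. A floor of 3 counts was 17.3 CPM in the shallow library and 0.461 to 1.16 CPM in the others. Shares of counts were given 95% Wilson intervals. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Intermediate values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.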

Results

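Accessible chromatin was profiled in CD28+ immature single-positive thymocytes, cells past β-selection that carry CD4 but not yet surface CD3 or CD8. There were 3 groups of 3 libraries: unstimulated cells, and cells given 2.5 or 10 µL of ImmunoCult per 100000 cells for 24 h, each from the same 3 donors. Counts in the 72671 deposited regions totalled 7309502, 120308 and 2757747 in the unstimulated libraries of donors 1, 2 and 3. They totalled 5287104, 5298930 and 2582596 at 2.5 µL, and 3678986, 3166682 and 2459806 at 10 µL. The unstimulated library of donor 2 was shallow: 57.5% of its regions held 0 counts, and 1 count was worth 5.78 CPM.

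**Figure D1:**
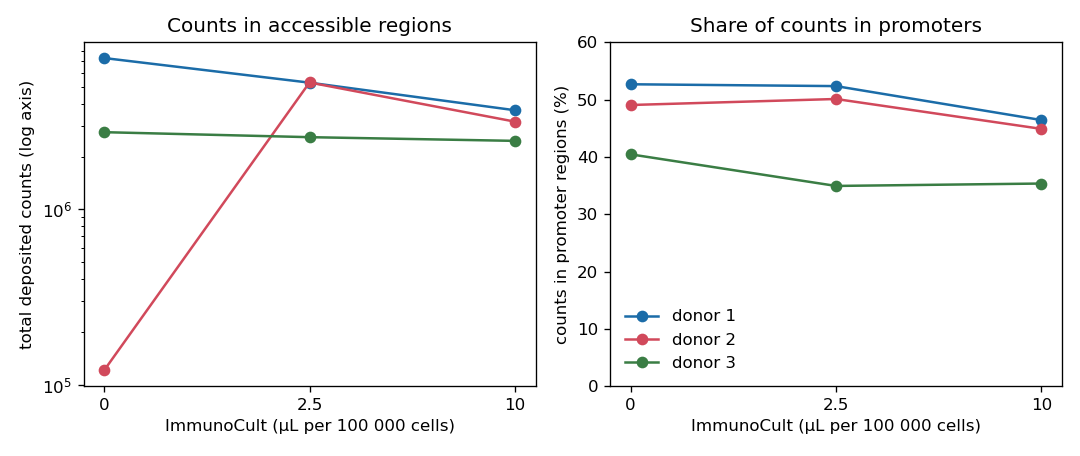
Left, total counts in accessible regions per library on a log axis, by ImmunoCult volume and donor, with 120308 counts in the shallow unstimulated library of donor 2. Right, the percentage of each library's counts that lay in promoter regions, which was 46.4%, 44.9% and 35.4% at 10 µL against 52.7%, 49.1% and 40.5% without stimulation.

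The first comparison asked which regions opened or closed in cells given 10 µL of ImmunoCult. A single region rose, inside an intron of PTPRN2, a gene for a transmembrane phosphatase-like protein of secretory granules. It lay on chromosome 7 at 158147647 to 158148148, 439814 bp from the nearest protein-coding TSS. Its level was 4.1 ± 3.58 CPM (mean ± SD, n = 3) without stimulation and 29.8 ± 29.6 CPM (n = 3) at 10 µL, a log2 fold change of 2.36 (SE 0.46, edgeR adjusted p = 0.0184). The rise was largest in donor 1, from 6.61 CPM without stimulation to 63.1 CPM at 10 µL (43 and 218 counts), beside 5.67 to 20.1 CPM in donor 3 (15 and 52 counts). No rise was shown in donor 2, with 6.21 CPM at 10 µL and 5.45 CPM at 2.5 µL (19 and 26 counts), where the shallow unstimulated library held 0 counts. Without the 10 µL library of donor 1 the log2 fold change was 1.17 (edgeR adjusted p = 1), and the call was also lost, at log2 fold changes of 2.27 to 2.75, without donor 2, without donor 3 or without any 1 unstimulated library.

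The next smallest p-values belonged to regions that did not pass the test. A region at 176840352 to 176840853 on chromosome 4 lay 47680 bp from the TSS of VEGFC, a growth factor of lymphatic vessels. It had 2.26 ± 2.1 CPM without stimulation and 14 ± 0.653 CPM at 10 µL (n = 3 each), with a log2 fold change of 2.17 (SE 0.5, edgeR adjusted p = 0.469). A region at 130824318 to 130824819 on chromosome 2, 12346 bp from the TSS of ARHGEF4, which encodes a guanine nucleotide exchange factor, had 2.92 ± 2.54 and 16 ± 2.31 CPM (n = 3 each). Its log2 fold change was 1.93 (SE 0.47, edgeR adjusted p = 0.956), and it passed with the donor as a replicate block (2.16, adjusted p = 0.0188). In both regions the shallow unstimulated library of donor 2 held 0 counts, where 1 count is worth 5.78 CPM, and this 0 pulls the unstimulated means down. Without stimulation donors 1 and 3 had 2.61 and 4.16 CPM in the VEGFC region, and 4.61 and 4.16 CPM in the ARHGEF4 region. Intergenic regions starting at 124902110 on chromosome 5 and at 78160732 on chromosome 13 had log2 fold changes of 1.73 and 2.27 (edgeR adjusted p = 1 for both). At an unadjusted p under 0.05 there were 1322 regions, of 70538 tested, fewer than chance alone would give if no region changed. The planned test has no term for the donor, and in simulated counts it recovered 0% of changes by a fold of 2. Its lack of calls is therefore weak evidence that regions did not change. DESeq2 and limma called 0 regions, with 795 and 984 at an unadjusted p under 0.05.

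Of the gene lists, 1 of 18 passed the test at 10 µL. Regions near constitutive genes, such as those for actin and ribosomal or proteasomal proteins, lay lower than other regions, with a median log2 fold change of -0.10 against 0.07 for the rest (62 regions of 19 genes, camera adjusted p = 0.00892). With an estimated correlation the list was not called (adjusted p = 0.904). None of these 62 regions was called alone, with 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Those 2 were rises, near B2M and PPIA, against the direction of the list. Among them, the ACTB promoter region had a log2 fold change of -0.84, a region 82187 bp from YWHAZ -1.13, and regions near B2M and PPIA 1.26 and 1.24. DESeq2 size factors and library size alone kept the negative median, at -0.03 and -0.09, below medians of 0.16 and 0.12 over all regions.

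The lists of T cell biology did not pass with all of their regions. T cell activation genes, such as CD69, EGR1 and NR4A1, had a median log2 fold change of 0.10 (235 regions of 34 genes, adjusted p = 0.994). Cytokine and chemokine genes had 0.12 (74 regions, adjusted p = 0.56), and TCR complex and proximal signalling genes 0.11 (219 regions, adjusted p = 0.994). AP-1, NFAT and NF-kB family genes, which encode the transcription factors downstream of the TCR, had -0.01 (118 regions, adjusted p = 0.138), where the mean was 0.00. Pre-TCR and immature thymocyte genes had -0.03 (164 regions, adjusted p = 0.134). CD4 CD8 double-positive stage genes had 0.00 (179 regions, adjusted p = 0.276), and positive selection and maturation genes 0.08 (222 regions, adjusted p = 0.994). With promoter regions only, set against all other regions, 4 lists passed: constitutive genes (median -0.27, adjusted p = 0.000221), AP-1, NFAT and NF-kB family genes (-0.30, 34 regions, adjusted p = 0.000141), apoptosis genes (-0.12, adjusted p = 0.0228) and double-positive stage genes (-0.07, adjusted p = 0.0392). These calls used the preset correlation. An estimated correlation was tried only with all regions of a list, and no list was called with it. Within 25 kb, again at the preset correlation alone, AP-1, NFAT and NF-kB family genes (-0.11, adjusted p = 0.00399), constitutive genes (-0.11, adjusted p = 0.00399) and apoptosis genes (-0.10, adjusted p = 0.00476) passed. Set against other promoters, a test chosen after seeing the data, constitutive genes and AP-1, NFAT and NF-kB family genes passed (adjusted p = 0.0397 for both), where other promoters had a median of -0.08. This test too was run at the preset correlation alone.

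Apoptosis genes had a median of 0.07 (adjusted p = 0.36), interferon-stimulated genes 0.01 (adjusted p = 0.716), and HOXA cluster genes -0.00 (adjusted p = 0.899) with a mean of 0.08. Among lists of other cell types, the medians were 0.08 for stem and early progenitor genes (adjusted p = 0.899), 0.04 for B cell genes (0.704), 0.14 for myeloid genes (0.994), and 0.01 for NK and innate lymphoid genes (0.806). They were -0.20 for erythroid genes (0.138), 0.18 for dendritic cell genes (0.276) and 0.09 for thymic epithelial and stromal genes (0.994), where the values in parentheses are camera's adjusted p. Camera's direction was down, against a positive median, for the double-positive stage, apoptosis, interferon-stimulated, stem, B cell, myeloid and NK lists.

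**Figure D2:**
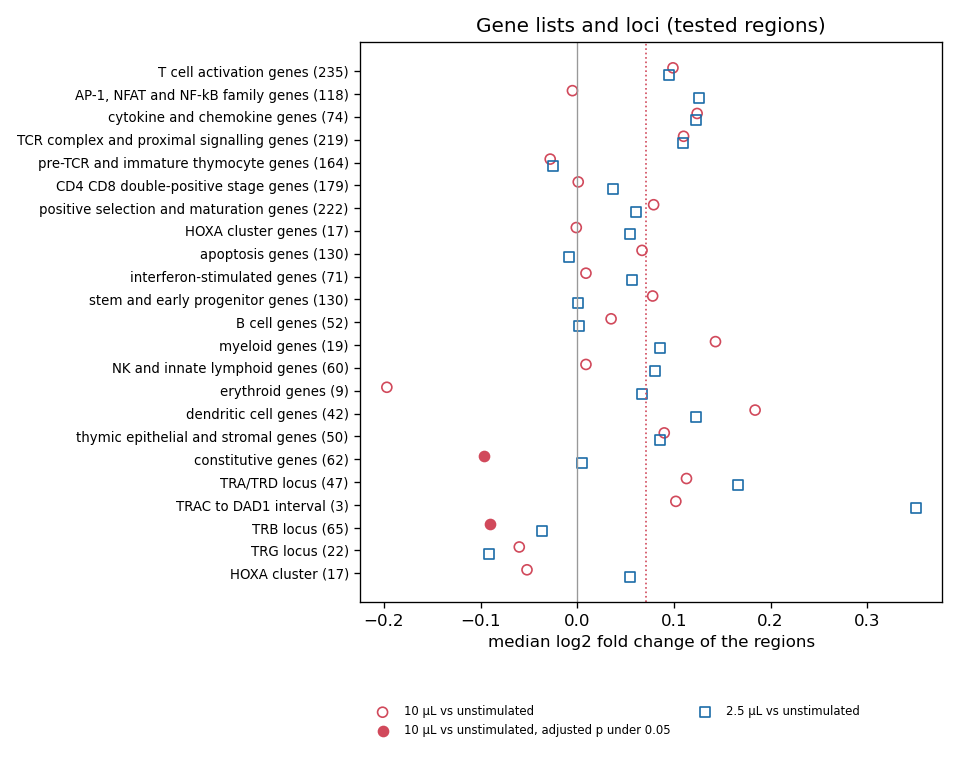
Median log2 fold change against unstimulated cells of the regions of each gene list or locus, with the number of regions in parentheses, for 10 µL (circles) and 2.5 µL (squares), 3 libraries per group. Filled circles passed camera at an adjusted p under 0.05 at 10 µL, which constitutive genes and the TRB locus did; the dotted line is the median over all regions at 10 µL, 0.07.

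Of the antigen receptor loci, the TRB locus, which holds the segments of the TCR β chain, had a median log2 fold change of -0.09 at 10 µL over its 65 regions on chromosome 7, between 142299177 and 142813399 (camera adjusted p = 0.00502). It was not called with an estimated correlation (adjusted p = 0.727) or without donor 1, where the median was 0.09 (adjusted p = 0.213). In the planned test 25 of its regions had positive values. No single TRB region was called, the smallest p being at 142478405 (log2 fold change -0.83). The region between TRBC2 and TRBV30, the interval with the TCR β enhancer, had -0.35. DESeq2 size factors and library size alone gave TRB medians of -0.00 and -0.04.

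The other loci did not pass. The TRA/TRD locus had a median of 0.11 over 47 regions (adjusted p = 0.788), and the region with the smallest p, at 21846264 on chromosome 14, had 0.78. The 3 regions between TRAC and DAD1, the interval with the TCR α enhancer, had 0.48, 0.10 and -0.05 (adjusted p = 0.766 for the interval). The TRG locus had -0.06 over 22 regions (adjusted p = 0.199), led by a region at 38193438 on chromosome 7 with 0.92. The HOXA cluster had -0.05 over 17 regions (adjusted p = 0.585) with a mean of 0.03, led by a HOXA2 exon with 1.71. The TRAJ segments and the interval from TRDJ3 to TRDC held 0 of the deposited regions, so they could not be compared.

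With the donor as a replicate block, 3 regions rose at 10 µL and 0 fell, with 4962 at an unadjusted p under 0.05. They were the PTPRN2 intron region, a second region of that intron at 158146984 and the region near ARHGEF4, and the second region was chosen after its values were seen. The list and locus calls were the same under that block, constitutive genes and the TRB locus. With the block and an estimated correlation, a setting chosen after seeing the data, neither was called (adjusted p = 0.994 and 0.391).

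The shallow unstimulated library was then left out while the replicate block was kept, a fit chosen after seeing the data. In it 279 regions fell and 47 rose at 10 µL, of 71918 tested. The balance depended on the scaling: with library size alone 28 fell and 31 rose, with loess offsets 5 and 86, and with GC offsets 170 and 30. The falls lay mostly in promoters: 243 of 279 (87.1%), against 24.2% of the regions that did not fall (odds ratio 21.2, Fisher's exact p = 5.2e-109 across regions, which are not independent replicates). The falls had more signal than most regions, with a median log2 CPM of 5.75 against 3.05 for all regions tested. At log2 CPM between 4.45 and 6.63, 3.03% of 7383 promoter regions and 0.92% of 2939 other regions were called as falls, a smaller difference at like signal. The median log2 fold change of the 279 falls was -0.87 (median SE 0.20). Without the 10 µL library of donor 1 the fit called 0 regions, so the calls needed that library. The 279 regions had a median of -0.83 there, and one of -0.74 without the unstimulated library of donor 3 (median SE 0.28 in both). These regions were picked for their fall with all of these libraries in the fit, so the medians cannot tell whether 1 library caused the fold. Loess offsets left 5 of the 279 falls called, at a median of -0.48, and GC offsets 126, at a median of -0.75.

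In this blocked fit, regions at genes of several kinds were among the largest falls. A region over untranslated sequence near the start of FOXO4, which encodes a forkhead factor of the AKT pathway, had 14.1 ± 0.449 CPM in the unstimulated libraries (n = 2) and 4.93 ± 2.63 CPM at 10 µL (n = 3), a log2 fold change of -1.47 (edgeR adjusted p = 0.0441). A region in an intron of MNT, a MAX-binding repressor, fell by 1.17 (edgeR adjusted p = 0.00696), one at the TSS of ARID1B, a subunit of the BAF chromatin remodelling complex, by 1.17, and one in an intron of the zinc finger gene ZNF846 by 1.35 (adjusted p = 0.0277 for both). Falls were also called at GRIN1 (-1.45), ATP9B (-1.28), PPP1R37 (-1.27), DNAAF3 (-1.19), MAGIX (-1.19) and SLC35B2 (-1.15). Named rises were at ARHGEF4 (2.13, adjusted p = 0.00696), VEGFC (2.09, adjusted p = 0.0109), TTC39C (1.53) and FAM120B (1.02). With loess offsets, 2 of the 10 named falls and 3 of the 4 named rises were called, and with GC offsets 5 and 4.

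**Figure D3:**
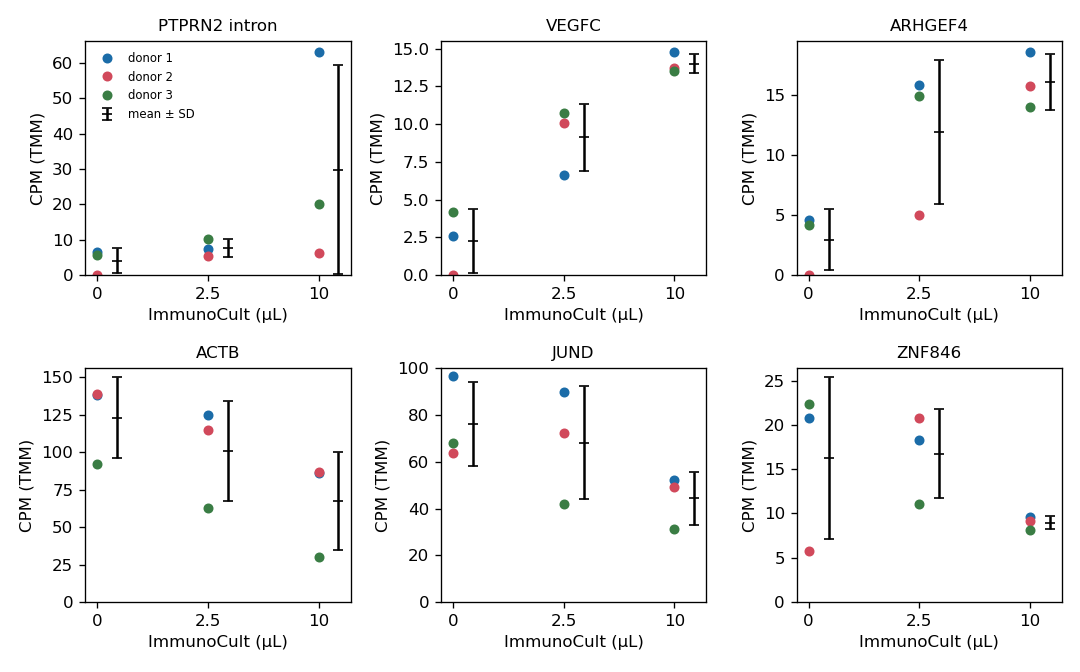
Level of 6 regions in each library (TMM-scaled CPM, all 9 libraries scaled together) by ImmunoCult volume, with the mean ± SD of the 3 libraries of a group in black. The 10 µL libraries of the PTPRN2 intron region spread widely around 29.8 CPM, while the VEGFC region had 14 ± 0.653 CPM there; the unstimulated library of donor 2 is shallow, and its points are the least precise.

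In the same blocked fit without the shallow library, regions of 8 lists were called. Constitutive genes had 4 falls among 62 regions, with 13 falls and 1 rise adjusted over the list alone, among them ACTB (-1.01), YWHAZ (-0.91) and POLR2A (-0.76). AP-1, NFAT and NF-kB family genes had 3 falls among 119 regions, with 10 adjusted over the list alone, at NFATC3 (-1.13), JUND (-0.97) and ATF3 (-0.83). A JUNB promoter region had -0.83 (adjusted p = 0.0561) and was not called. Apoptosis genes had 2 falls, both at BBC3 (-0.96 and -1.12), which encodes the BH3-only protein PUMA. There was 1 fall each at GADD45B (-0.85, T cell activation genes), TGFB1 (-1.06, cytokine genes), BCL2L1 (-0.80, double-positive stage genes), CEBPB (-0.95, myeloid genes) and ID2 (-0.80, NK and innate lymphoid genes), and 0 rises in any of these lists. With loess offsets none of these 14 falls was called, at a median of -0.53 against -0.94 without them. With GC offsets 7 of the 14 were called, at a median of -0.77, and the falls at ATF3, GADD45B, TGFB1, BCL2L1, CEBPB and ID2 and one of those at BBC3 were not.

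By camera in that fit, constitutive genes (median -0.21, adjusted p = 5.15e-06), AP-1, NFAT and NF-kB family genes (median -0.09, adjusted p = 0.0369) and pre-TCR and immature thymocyte genes (median -0.16, adjusted p = 0.0369) lay lower at 10 µL. None of these 3 lists was called with an estimated correlation (adjusted p = 0.465, 0.465 and 0.505). The pre-TCR list had 0 called regions, 3 adjusted over the list alone, and HES1, TCF3, ID1 and ID3 regions with -0.84, -0.74, -0.72 and -0.65. With GC offsets, AP-1, NFAT and NF-kB family genes were not called (median -0.06, adjusted p = 0.202), and constitutive genes (-0.16), pre-TCR and immature thymocyte genes (-0.15) and double-positive stage genes (-0.12) were (adjusted p = 2.85e-05, 0.0258 and 0.0313). Of the loci, TRB was called in that fit (median -0.18, adjusted p = 0.00475), with 1 fall among its 65 regions, at 142357900 on chromosome 7 (-1.05). With an estimated correlation it was not (adjusted p = 0.468).

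The share of counts in promoter regions was lower at 10 µL in each donor. It was 52.7%, 49.1% and 40.5% without stimulation and 46.4%, 44.9% and 35.4% at 10 µL, a mean difference of -5.17 percentage points (SD 1.04, n = 3). The 95% Wilson interval was within 0.283 points of each value in the shallow library and within 0.06 in the others. The exact sign-flip permutation test, two-sided, gave p = 0.25, the smallest p that 3 pairs allow. The mitochondrial-like regions, whose sequence resembles the mitochondrial genome, held 1.17%, 5.47% and 1.74% of the counts without stimulation and 2.14%, 2.41% and 2.12% at 10 µL.

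Promoters and motifs were counted among the regions called by the planned test. The single rise was not a promoter (0 of 1, Fisher's exact p = 1), and 0 of 22 motifs passed, with a smallest unadjusted exact p of 0.238. In the 279 falls of the blocked fit without the shallow library, 3 of 22 motifs passed against regions matched on GC content. The KLF/SP motif was found in 24.7% against 13.9% (adjusted exact p = 6.67e-05), the CAGCTG E-box in 10% against 16.4% (0.0253) and the CAGGTG E-box in 12.2% against 19.3% (0.0246). With promoter status matched too, KLF/SP passed (adjusted exact p = 0.000954) and the E-boxes did not. In the central 400 bp, matched on GC content, KLF/SP and CAGCTG passed and CAGGTG did not (adjusted exact p = 8.36e-10, 0.000557 and 0.121). Signal was not matched in these tests, and the falls had a median log2 CPM of 5.75 against 3.05 for all regions tested. The motif shares therefore cannot be told apart from a difference in signal. In the 47 rises, 0 of 22 motifs passed, the STAT motif having the smallest p, with 23.4% against 9.3% (adjusted exact p = 0.0962). In the central 400 bp STAT passed, with 38.3% against 16.6% (adjusted exact p = 0.0121), and against regions not matched on GC content STAT and NFAT did (0.000201 and 0.00444). With GC content and promoter status both matched, neither passed (adjusted exact p = 0.113 and 0.629). Distance to a TSS was not matched, and 21 of the 47 rises lay over 500 kb from one.

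The second comparison asked what 2.5 µL of ImmunoCult did. The smallest p-values were at a region 18843 bp from the TSS of CNGA1, a cyclic nucleotide-gated channel gene, and at an intron of HCRTR2, an orexin receptor gene. The CNGA1 region had 10.9 ± 3.77 CPM without stimulation and 2.77 ± 0.657 CPM at 2.5 µL (n = 3 each), with a log2 fold change of -1.94. The HCRTR2 region had 1.32 ± 1.24 and 8.47 ± 0.899 CPM (n = 3 each), with 2.06. Intergenic regions starting at 63360255 on chromosome 9, 25409995 on chromosome 21 and 851051 on chromosome 3 had 1.96, 1.69 and 1.96. None of the 5 passed (edgeR adjusted p = 1 for all). edgeR called 0 regions, with 700 at an unadjusted p under 0.05, and DESeq2 and limma called 0, with 306 and 386. These counts too were below what chance alone would give if no region changed.

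No gene list passed at 2.5 µL, with camera adjusted p from 0.832 to 0.98. The medians were 0.10 for T cell activation genes, 0.12 for cytokine and chemokine genes, 0.13 for AP-1, NFAT and NF-kB family genes, and 0.00 for constitutive genes, beside 0.07 over all regions. The loci did not pass either, with medians of -0.04 for the TRB locus (adjusted p = 0.24), -0.09 for the TRG locus (0.24), 0.17 for the TRA/TRD locus (0.274), 0.35 for the TRAC to DAD1 interval (0.24) and 0.06 for the HOXA cluster (0.496). With the replicate block, the TRB and TRG loci lay lower, with medians of -0.06 and -0.13 (adjusted p = 0.0361 for both), but with the block and an estimated correlation, chosen after seeing the data, neither was called (adjusted p = 0.639 and 0.409). The region with the smallest p was at 142646343 in TRB (0.68), at 38340334 in TRG (0.60), at 21923790 in TRA/TRD (0.58), at 22561672 between TRAC and DAD1 (0.37) and in HOXA2 in the HOXA cluster (0.90). Counts in promoters differed by -1.6 percentage points on average (SD 3.47, n = 3, exact sign-flip permutation p = 0.75).

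The third comparison set the 2 doses against each other. The PTPRN2 intron region on chromosome 7 had the smallest p, with a log2 fold change of 1.99 (SE 0.41, edgeR adjusted p = 0.0809) from 7.68 ± 2.47 CPM at 2.5 µL (n = 3). A region at 52056355 on chromosome 8 had 1.80, a region 30293 bp from CEP68, which encodes a centrosomal protein, 2.04, the second PTPRN2 intron region 1.32 and a region at 126447402 on chromosome 6 2.54. None passed (edgeR adjusted p = 1 for these 4). edgeR called 0 regions, with 695 at an unadjusted p under 0.05, and DESeq2 and limma called 0, with 306 and 75, again below what chance alone would give.

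Between the doses, no list passed. The lowest adjusted p were those of constitutive genes (median -0.13, adjusted p = 0.0723) and of AP-1, NFAT and NF-kB family genes (median -0.10, adjusted p = 0.0752). With the replicate block both passed, with medians of -0.15 and -0.11 (adjusted p = 0.00212 and 0.0409), but with the block and an estimated correlation, chosen after seeing the data, neither did (adjusted p = 0.937 for both). With the block and GC offsets and without the shallow library, AP-1, NFAT and NF-kB family genes did not pass (adjusted p = 0.255). Without the block and with promoter regions only, they passed with -0.33 (adjusted p = 9.38e-05) and constitutive genes with -0.38 (0.000154). The TRB locus had a median of -0.10 (adjusted p = 0.117), and no locus passed. The smallest p lay at 142434179 in TRB (0.56), at 38193438 in TRG (1.16), at 21923790 in TRA/TRD (-0.995), at 22556273 between TRAC and DAD1 (-0.40) and at 27179725 in the HOXA cluster (-0.60). Counts in promoters differed by -3.58 percentage points on average (SD 3.48, n = 3, exact sign-flip permutation p = 0.5).

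The responses to both doses were compared across regions. No region was called at 2.5 µL, so none could be called at both doses. The log2 fold changes of the 70538 regions correlated at r = 0.584 with a covariance of 0.102, and 68.4% had the same sign. Both doses share the unstimulated libraries, so 20 simulations of unchanged groups against them gave r = 0.357 on average (0.347 to 0.368), a covariance of 0.078 and 61.9% of the same sign. On average 1.5 regions were called at both doses in these simulations. The simulated groups were drawn from means over all 9 libraries, which include the unstimulated ones, and this would make the simulated covariance too low. The covariance was 0.024 above the simulated one, and part or all of the excess may come from the shared unstimulated libraries, which were too few to split. It may also come from the shared donors, which the simulations left out: the 2.5 and 10 µL libraries of donors 1, 2 and 3 correlated at 0.359, 0.433 and 0.558 in their deviations from the group means. Regions are not independent replicates.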

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

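No called result changed the direction of its test under any setting run, but the median of the TRB locus at 10 µL turned positive without donor 1, from -0.09 to 0.09. Of 1778 values of single regions, lists and loci under the settings planned beforehand, 1682 kept their direction and their side of the threshold. Of the rest, 51 changed direction without passing the threshold in either setting, 28 passed it newly and 17 no longer passed it. Of 1140 values under settings chosen after seeing the data, 876, 34, 221 and 9 did so. Few of these values passed the threshold in the planned test, so keeping their side mostly meant not being called in either setting. The shares therefore do not show how firm the calls are. For 10 µL against unstimulated the planned edgeR test called 1 region, as did library size alone, no filter and autosomes alone. It called 0 at an adjusted p under 0.01, with DESeq2, DESeq2 size factors, loess offsets, the stricter filter, the 6 libraries compared or limma-trend, and 0 with the replicate block and loess offsets. The replicate block called 3. Leaving out 1 donor or library gave 0 to 2. The PTPRN2 call was lost without any 1 donor, any 1 unstimulated library or the 10 µL library of donor 1, and was kept without the 10 µL library of donor 2 or 3. The 2 calls without the unstimulated library of donor 3, named after their values were seen, were at 40387821 and 41447009 on chromosome 10.

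The settings that left out the shallow unstimulated library, or weighted it down, were chosen after seeing the data. With the replicate block they called 326 regions at 10 µL against unstimulated (47 rises, 279 falls), 91 with loess offsets (86 and 5), 200 with GC offsets (30 and 170), 59 with library size alone (31 and 28), 1296 in DESeq2 (46 and 1250), 61 without donor 2 (18 and 43), 2140 by voom with library weights (1156 and 984) and 225 after thinning (26 and 199). The voom fit kept all 9 libraries. It gave the shallow library a weight of 0.6996, little below the 0.7281 of the 2.5 µL library of donor 3. Its calls are therefore not calls without the shallow library. Without a further library they called 147 (unstimulated, donor 1), 2 (unstimulated, donor 3), 0 (10 µL, donor 1), 55 (10 µL, donor 2) and 906 (10 µL, donor 3). At 2.5 µL against unstimulated they called 0, except 6 with loess offsets, 37 by voom and 1 without the 2.5 µL library of donor 2. Between the doses they called 0, except 8 with loess offsets, 2 by voom, 1261 without the 2.5 µL library of donor 3, 32 without the 10 µL library of donor 3, and 1 each with GC offsets, thinning, donor 2 left out, or without the 2.5 µL or the 10 µL library of donor 2. In the planned test between the doses, library size alone called 1 and leaving out 1 donor or library 0 to 8, the 8 being without the 2.5 µL library of donor 3.

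At 10 µL against unstimulated, 1 list was called, 0 with an estimated correlation (with or without the replicate block) or fry, 4 with promoter regions only, 2 with these against other promoters, 3 within 25 kb, and, in the replicate block without the shallow library, 3, 3 with GC offsets (2 of them the same) and 0 with an estimated correlation. Between the doses 0 lists were called, but 2 with the replicate block with or without the shallow library, 1 with GC offsets, 6 with promoter regions only, 3 with these against other promoters, 4 within 25 kb and 1 each with library size only and DESeq2 size factors. Of the loci, 1 was called at 10 µL against unstimulated, 0 with an estimated correlation (with or without the replicate block) or fry, 2 with GC offsets, and 0 to 2 without 1 donor. At 2.5 µL 0 were called, but 2 with the replicate block, 2 without the shallow library, 2 with GC offsets and 0 to 2 without 1 donor. Between the doses 0 were called, but 1 with GC offsets and 0 to 1 without 1 donor. The promoter share of calls was 0% in the planned test and 87.1% among the falls of the replicate block without the shallow library, where 3 motifs passed against 0. The replicate block changed no other call of a list or locus. Fewer libraries or regions account for part of the loss in the leave-outs, and otherwise the cause was not tested. The unstimulated library of donor 2 had 57.5% of regions at 0, but in simulated counts the replicate block recovered about as many changed regions with it as without it. Those counts gave every library the same dispersion per region, so noise of the shallow library beyond its low total was not simulated. The planned test was not simulated without it.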

Other observations

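Of the tests below, those of GC offsets, of dose relabelling, of the falls without 1 library, of the matched promoter difference by donor and without 1 library, of histone against matched promoters, of the chromosome 7 rise without 1 library and of all splits of the samples were chosen after the result was seen.

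Promoters of replication-dependent histone genes, which are transcribed in S phase, lay lower at 10 µL than in unstimulated cells, in the fit with the replicate block and without the shallow library. Of their 65 promoter regions at 53 genes, 64 had negative log2 fold changes, with a median of -0.59. Called falls, chosen after their values were seen, were 9 regions, at H3C14, H2AC18, H2AC19, H3C15, H4C15, H2AC20 and H2AC25 on chromosome 1 and at H3C2 and H3C8 on chromosome 6. The median difference between 10 µL and unstimulated was -0.60 in donor 1 and -0.53 in donor 3, and that between 10 and 2.5 µL was -0.47, -0.41 and -0.04 in donors 1, 2 and 3. The median was -0.31 in the planned test, with 0 calls, and -0.25 and -0.32 there with DESeq2 size factors and with library size alone.

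Of the 47 rising regions of that fit, none was a promoter, 21 were over 500 kb from a TSS, as were 6.57% of the regions tested, and 15 were within 100 kb of one. Their median log2 fold change was 1.71 and their median GC content 39.9%, beside 50.1% for all regions. With loess offsets 86 regions rose, 20 of them shared, and these held all 11 regions of mitochondrial-like sequence and 59 regions over 500 kb from a TSS.

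The first pattern weighed is the fall of promoters at 10 µL, 279 falls in the replicate block without the shallow library, with a median log2 fold change of -0.873 (quartiles -0.954 and -0.816). Lower signal over background in the 10 µL libraries would lower every region of like signal, while at matched signal promoters differed from other regions by a log2 fold change of -0.119 (95% bootstrap interval -0.14 to -0.102). That interval covers the regions of 1 fit and no spread between donors, of which 2 had both libraries (-0.148 and -0.108). Between 10 and 2.5 µL the value was -0.21, -0.048 and 0.055 in donors 1, 2 and 3. It came to -0.073 without the 10 µL library of donor 1 and to -0.089 without the unstimulated library of donor 3, short of the bound of -0.1 set beforehand. Without each other library it was -0.179 to -0.135. Whether lower signal over background is the whole cause therefore stays open. It may be a large part, since other regions of like signal also had a median of -0.182 beside -0.344 in promoters, and loess offsets, which remove any trend with signal, brought the falls to a median of -0.479 (quartiles -0.615 and -0.383) and left 5 calls. With GC offsets the median was -0.745 and 126 of the 279 falls were called, so a smooth trend with GC content took away little of the median. These regions were picked for their fall without GC offsets, so the median cannot tell whether GC content is the whole cause. After thinning to equal total counts it was -0.887. The fit already scales for totals and thinning keeps the proportions of a library, so this value cannot tell whether total counts play a part. As many regions were called in 2 of 72 relabellings of the doses within donors. They were the real one and a swap of 10 µL and unstimulated labels in donors 1 and 3 together with a swap of the 2.5 and 10 µL labels in donor 2 (692). Whether 1 library is the cause of the fold stays open, since the 279 regions were picked for their fall in the fit that held all of these libraries. Without the 10 µL library of donor 1 the falls had a median of -0.828 (quartiles -0.972 and -0.732). Without the unstimulated library of donor 3 they had one of -0.74 (quartiles -0.853 and -0.663), the value nearest 0 among the 5 libraries left out in turn. Their calls ended (0 of 279 in both) as the median SE rose from 0.203 to 0.281, so the calls were not kept. Whether the cells responded was not tested.

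The second pattern weighed is the lower histone promoters. A general fall of promoters of like signal and GC content gave a median of -0.292 (central 95% from -0.379 to -0.22) over 10000 matched sets of other promoters, beside -0.589 in the histone promoters. Since the histone genes were chosen after their falls were seen and lie in clusters, this does not test whether they fell more than other promoters, which stays open. Reads shared between near-identical histone copies are unlikely to be the whole cause, since the 43 promoters with under 5% shared sequence had a median of -0.562. With GC offsets 15 regions fell at a median of -0.64, but with loess offsets 0 were called at a median of -0.235, and without the 10 µL library of donor 1 there were 0 calls at -0.567. Fewer cells in S phase at 10 µL may be behind it, as a hypothesis that a measurement of DNA content in cells of each dose would test, and none was analysed here.

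The third pattern weighed is the rise in the PTPRN2 intron on chromosome 7. Without the 10 µL library of donor 1 the log2 fold change was 1.169 (edgeR adjusted p = 1), beside 2.36 with it, so that library carried much of the fold. Whether it is the whole cause stays open. Donor 3 also rose, from 5.67 to 20.1 CPM, and the reduced fit had an unadjusted edgeR p of 0.0307. The region was picked for its small p with donor 3 in the fit, so neither value can decide it. A difference of donor 1 or of its 10 µL library was not told from a response to the dose by any test run.

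The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For regions, the real splits called 1, 0 and 0 at 10 µL against unstimulated, 2.5 µL against unstimulated and 10 against 2.5 µL, and the highest other splits 614, 4585 and 1729, with 6, 10 and 10 splits as high as the real one. For lists the real splits called 1, 0 and 0, the highest others 1, 2 and 1, with 3, 10 and 10 as high. For loci they called 1, 0 and 0, the highest others 1, 4 and 2, with 2, 10 and 10 as high. The splits with 614, 4585 and 1729 calls keep libraries of a donor together, which points to a donor structure of the samples. Splits that part all 3 donors, as the real one does, called at most 1, 0 and 0 regions.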
